A study of Marchantia polymorpha with 12 samples.

How the data were processed

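RNA was measured by sequencing in 12 libraries of Marchantia polymorpha. Per the labels' protocols, plants were subcultured for 3 weeks on agar, apical fragments without gemma cups were taken (the tissue label reads "Leaflets"), wounding was done with tweezers, and samples were frozen 2 h later. Each replicate was an independent pool of 6 to 8 plants, and the sequencing libraries were prepared by Novogene, per the same protocols. The 4 groups are mock and wounded Tak-1 and mock and wounded double mutant, with 3 libraries each.

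The table as deposited holds raw gene counts, 1 column per library, which the authors did not normalise as far as the values show: they are whole numbers with a different total in each library. Trim Galore (a read trimmer), HISAT2 (an aligner), HTSeq (a read counter) and edgeR are named in the submitters' processing notes, without versions, settings or the step each was used for. The genome build and annotation are not given in the sources used here, and neither is the strandedness of the libraries. A pair of wounded mutant columns shares a single header, so these libraries were used as members of their group and written as A and B, in the order of the table. Every column of values was used.

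Gene IDs were matched to locus tags of a reference gene table of assembly MpTak2_v7.1, which served for names and for the order of neighbouring genes. Of 20574 IDs, 17641 matched, holding 99.1% of the counts, and 3091 of these carry a symbol. Among the 13726 tested IDs, 13184 matched and 2538 have a symbol. IDs with a symbol hold 18.8% of the counts, so the gene lists and named genes describe a minority of the transcripts.

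Totals per library ran from 19121900 to 30821817 counts. A floor of 3 counts corresponds to 0.0937 to 0.158 CPM per library, and the lowest detectable level is of that size. Floors and the 95% counting intervals cover counting error only, since reads without molecular identifiers are not independent molecules. The 20 most abundant genes held 6.21 to 9.18% of the counts of each library. Reads of similar members of a gene family (dirigent proteins, peroxidases, LEA proteins, polyphenol oxidases) may be shared or discarded in counting, so single members of such families are uncertain.

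Counts were analysed with R 4.3.3 and edgeR 4.0.16. Genes were kept by filterByExpr by group, libraries were scaled by TMM, and a quasi-likelihood model with 1 mean per group was fitted to all 12 libraries (8 residual and 4.46 prior degrees of freedom; common biological coefficient of variation 0.121). A total of 5 contrasts were tested, all two-sided: wound against mock in Tak-1, wound against mock in the mutant, the difference of these responses (mutant minus Tak-1), and mutant against Tak-1 in mock and in wounded plants. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested in that contrast. Adjusted p-values of genes are those of edgeR unless another tool is named. CPM are over the TMM-scaled totals of the tested genes and given as mean ± SD, and log2 fold changes come from the fit. The SE of a log2 fold change is its absolute value over the square root of the quasi-likelihood F statistic. Such an SE can be too small for large changes from few counts. A group at 0 counts was compared through a floor of 3 counts over the group.

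Gene lists were defined by symbol, since the table gives no product descriptions, and were tested with camera of limma 3.58.1 (preset correlation between genes 0.01, log2 CPM with prior count 2, at least 3 tested members, Benjamini-Hochberg over the lists of a contrast). The lists tested were fatty acid desaturases (FAD, DES), lipoxygenases and CYP74 (jasmonate and oxylipin synthesis), jasmonate signalling (JAZ, COI1, NINJA, TPL), phenylpropanoid and flavonoid enzymes, dirigent proteins with laccases and polyphenol oxidases (DIR, LAC, PPO), class III peroxidases (POD), terpene and isoprenoid enzymes, defence proteins (PR, Cupin, GH17, GH18, GH19), heat shock proteins, glutathione transferases and detoxification (GST, UGT, MATE, ABCB, ABCC, ABCG), P450 enzymes, WRKY, AP2/ERF, and MYB and bHLH factors, calcium signalling, cell wall modification (Expansin, EXL, GH16, GH28, GH9), photosynthesis, chlorophyll synthesis, histones and DNA replication, lipid synthesis and transfer, abscisic acid and desiccation (PYL, LEA, DHN, SNRK), auxin and cytokinin, sperm and antheridium proteins, rhizoid and air pore proteins, and V chromosome genes (by ID). A list may hold members that other lists hold as well. Lists of ribosomal proteins, of U chromosome genes and of organelle genes had no tested members and give no result. Symbol patterns were written after the symbols had been seen but before any groups were compared. List medians were also computed with genes of 3 or fewer counts in a group at their bound or ratio, which moved 2 of 100 medians by more than 0.005.

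Groups, contrasts, tests, list themes, alternatives and the rule for naming genes were written before the data were examined. The rule names, per contrast, the 8 largest rises and 8 largest falls among called genes that changed at least 2-fold, have a mean of at least 5 CPM in the higher group and do not overlap between groups (for the difference of responses, 5 CPM in any group and no condition on overlap). It adds the 2 called members with the smallest adjusted p of each list, and the desaturases of the labels. Only genes with an informative symbol were named.

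The steps were tested on simulated data drawn from the real means and library sizes over 13726 genes. For the wound response in Tak-1, 64.2, 77.6 and 90.9% of genes changed 1.5, 2 and 4-fold were called, with 6 false calls. For the difference of responses the shares were 31.3, 65.7 and 81.8% with 4 false calls, and for the genotypes after wounding 43.3, 67.2 and 89.4% with 5. In each of these a changed list of 40 genes was called and 0 of 20 unchanged lists were. Genes were drawn independently there, while the estimated correlation was 0.243 for desiccation genes, 0.469 for WRKY factors and 0.603 for chlorophyll genes. False calls of lists with correlated members were therefore not tested.

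Alternatives were DESeq2 1.42.0 size factors and upper-quartile scaling in edgeR, the Wald test of DESeq2, no low-count filter, a filter at 1 CPM in 3 libraries, a fit on the groups of the contrast alone, the replicate number as a block, scaling without the 20 most abundant genes, a 2-fold threshold, and each library left out. For lists they were an estimated correlation, the test fry, and a prior count of 0.5. The relation between contrasts that share the Tak-1 mock libraries was set beside 100 simulations of unchanged groups. Fisher's exact test compared called genes in each list with the genes tested. Other splits of the libraries into groups of the same sizes were fitted in the same way.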

Results

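Gene transcripts were counted in 12 libraries of the liverwort Marchantia polymorpha, 3 in each of 4 groups. The plants were Tak-1, a male wild-type strain, and a double mutant in fatty acid desaturase genes that the labels name Mpfad3fad7. Each genotype was left unwounded (mock) or wounded with tweezers and frozen 2 h later. The Tak-1 mock libraries 1, 2 and 3 held 21771492, 19832049 and 30821817 counts, and the wounded Tak-1 libraries 30330355, 25231159 and 22860423. The mutant mock libraries held 25126393, 19121900 and 23598615 counts. Wounded mutant library 1 held 27436922 counts. The remaining pair of wounded mutant libraries carried the same column name, so they have no replicate number here. Unnumbered library A held 20439510 counts and unnumbered library B 28674354. CPM are a library's counts scaled to a common total, after TMM scaling. Correlations of log2 CPM between libraries of the same group, across genes, ran from 0.979 to 0.992. Between libraries of different groups they ran from 0.876 to 0.985, so the ranges overlap. Mutant mock library 1 correlated at 0.983, 0.979 and 0.985 with Tak-1 mock libraries 1, 2 and 3. With mutant mock libraries 2 and 3 it correlated at 0.982 and 0.979. The variance between libraries of the same group was 8.28 to 27.7 times that of counting error (chi-square per degree of freedom over 12 pairs). Of 20574 gene IDs, 13726 passed the low-count filter and were tested.

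The first principal component of log2 CPM held 69.7% of the variance and separated mock libraries, at scores of -75.2 to -51.5, from wounded ones, at 41.7 to 80.2. The second held 13.1% and separated Tak-1 libraries, at -45.6 to -11.0, from mutant libraries, at -2.49 to 42.5.

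**Figure D1:**
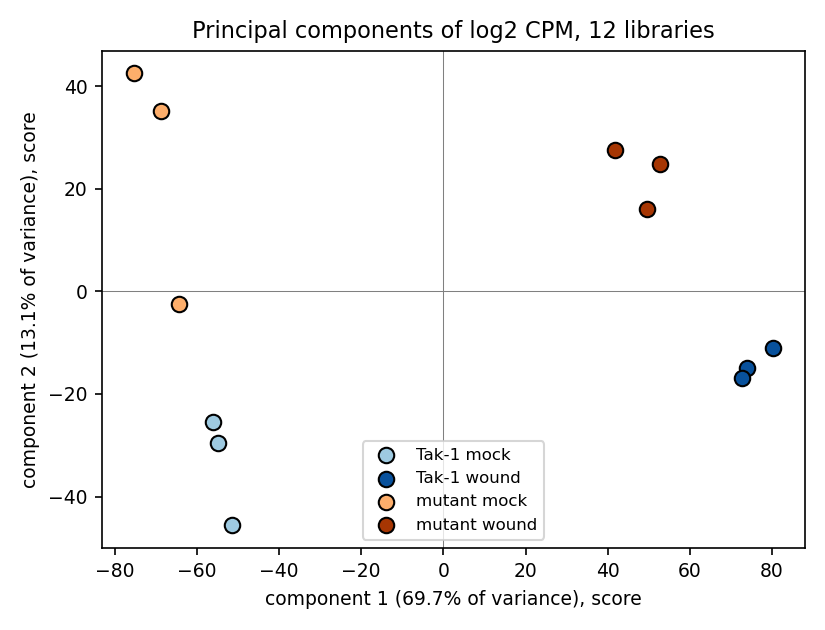
Scores of the 12 libraries on the first principal component (69.7% of the variance, horizontal) and the second (13.1%, vertical) of log2 CPM, each point a library coloured by group. Mock and wounded libraries lie on opposite sides of 0 on the first component, and Tak-1 lies below the mutant on the second.

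Desaturases insert double bonds into fatty acids, and omega-3 desaturases make the trienoic fatty acids from which jasmonates form. The titles name the mutated genes FAD3 and FAD7, and the growth protocol names them DES6 and FAD5. The reference table lists MpFAD3, MpDES5 (synonym MpFAD7), MpDES6 (synonym MpFAD12) and MpFAD5 as different genes, so each was measured. None of the 4 was called lower in the mutant. Transcript counts hold no information on edited sequence and such levels do not check a genotype. MpFAD3 (Mp2g24510) had 205, 217 and 218 CPM in Tak-1 mock libraries 1 to 3, 220, 210 and 237 CPM in the wounded ones, 250, 256 and 235 CPM in mutant mock libraries, and 248, 254 and 236 CPM in wounded mutant libraries 1, A and B. In the same order, MpDES5 (Mp3g13250) had 123, 124 and 132 CPM, then 180, 171 and 177, then 152, 137 and 140, then 194, 206 and 201 CPM. MpDES6 (Mp6g17330) had 78.6, 77.6 and 84.7 CPM, then 44.6, 30.5 and 38.9, then 106, 83.8 and 80.2, then 45.5, 45.8 and 42.7 CPM. MpFAD5 (Mp3g10660) had 234, 202 and 247 CPM, then 349, 373 and 359, then 295, 343 and 301, then 339, 378 and 339 CPM.

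MpFAD3 did not pass the test between genotypes, with log2 fold changes (mutant over Tak-1) of 0.21 in mock (adjusted p = 0.0680) and 0.15 after wounding (adjusted p = 0.127). DESeq2 called MpFAD3 higher in mock (adjusted p = 0.0147), and upper-quartile scaling called it higher after wounding (adjusted p = 0.0494). MpDES5 was not called in mock (0.18, adjusted p = 0.0887; called by DESeq2, adjusted p = 0.0215) and was 0.19 higher in the mutant after wounding (adjusted p = 0.0368). That call was lost without wounded Tak-1 library 1 (0.0513), 2 (0.101) or 3 (0.0699), and without wounded mutant library 1 (0.0618), A (0.117) or B (0.0867). MpDES6 differed by 0.17 in mock (adjusted p = 0.538) and 0.23 after wounding (adjusted p = 0.270), within the spread between replicates. MpFAD5 was 0.46 ± 0.08 (SE) higher in the mutant mock libraries (adjusted p = 0.0133), a call lost without Tak-1 mock library 2 (0.0567) or mutant mock library 2 (0.0604), and -0.03 after wounding (adjusted p = 0.833).

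Other desaturases did differ between the genotypes. MpFAD11 (Mp5g20700) was lower in every mutant library. It was at 525 ± 38.3 CPM in Tak-1 mock and 180 ± 14.4 CPM in mutant mock (log2 fold change -1.55 ± 0.10, adjusted p = 3.68e-06), and at 955 ± 103 against 197 ± 19.6 CPM after wounding (-2.27 ± 0.10, adjusted p = 1.35e-07; SD and SE, n = 3). MpFAD8 (Mp3g17690) was at 63.8 ± 11.3 CPM in Tak-1 mock and 13.5 ± 6.42 CPM in mutant mock (-2.23 ± 0.24, adjusted p = 0.000475). After wounding it was at 122 ± 10.03 CPM in Tak-1 and 20.7 ± 0.514 CPM in the mutant (-2.56 ± 0.23, adjusted p = 1.99e-05).

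**Figure D2:**
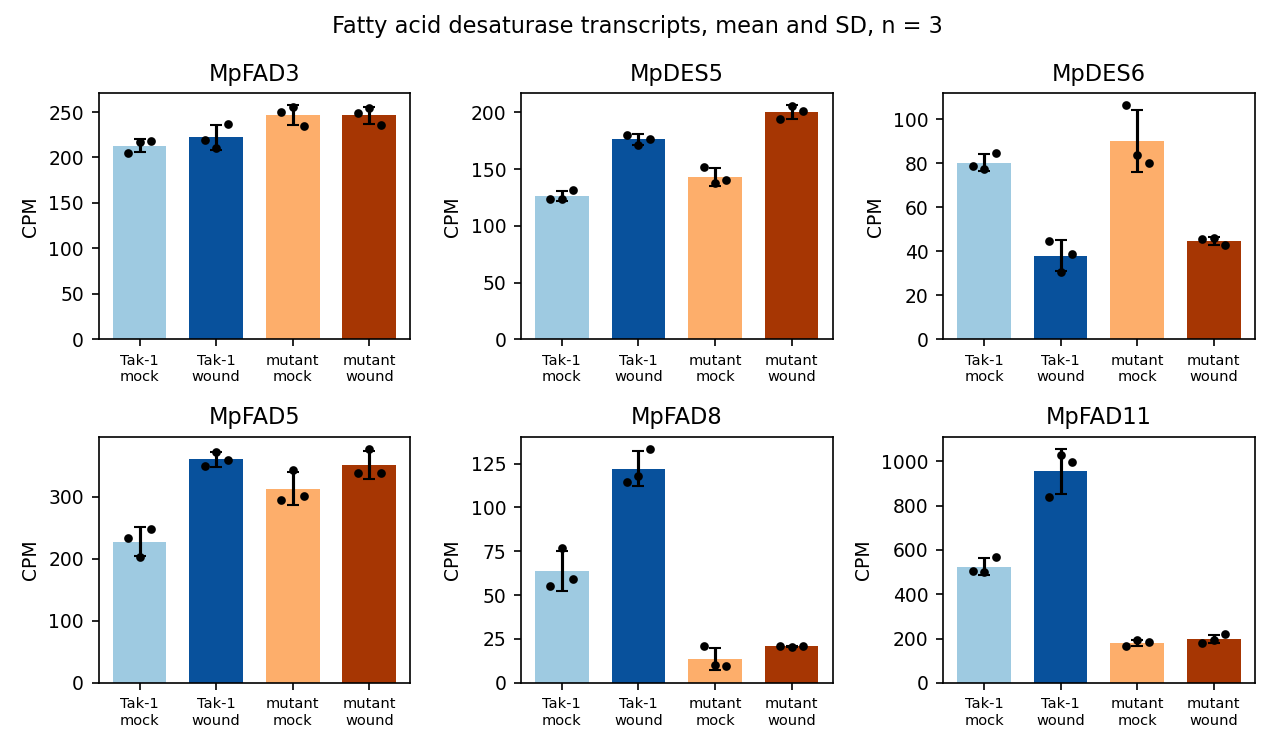
CPM (vertical, from 0) of 6 desaturases in the 4 groups: bars are means, error bars SD, points the 3 libraries of each group. MpFAD3, MpDES5, MpDES6 and MpFAD5 are transcribed in both genotypes, while MpFAD8 and MpFAD11 are lower in each mutant library than in any Tak-1 library.

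The first comparison asked which transcripts respond to wounding in plants with both desaturases intact. Single genes of lipid oxidation and jasmonate signalling rose in Tak-1. MpLOX2 (Mp2g23380), named as a lipoxygenase, an enzyme that adds oxygen to polyunsaturated fatty acids, rose from 235 ± 14.5 to 1908 ± 201 CPM (log2 fold change 3.02 ± 0.11, adjusted p = 3.31e-10). MpCYP74N2 (Mp5g16260), of the P450 family that holds allene oxide synthases, rose from 281 ± 17.5 to 1474 ± 153 CPM (2.39 ± 0.12, adjusted p = 4.34e-09). MpJAZ (Mp6g06230), whose product represses jasmonate signalling, rose from 28.6 ± 1.86 to 220 ± 24.8 CPM (2.94 ± 0.12, adjusted p = 6.73e-10). MpCOI1 (Mp2g26590), named for the jasmonate receptor COI1, fell by 0.58 on the log2 scale (adjusted p = 1.09e-06). MpPPO31 (Mp3g24060), named as a polyphenol oxidase, was at 0 counts in mock and 44.9 ± 14.7 CPM after wounding, at least 1103-fold higher against a floor of 3 counts over the group. MpBHLH51 (Mp8g06230) rose from 0.125 to 238 ± 36.2 CPM (10.76 ± 0.31, adjusted p = 7.89e-11). The 0.125 CPM lies near the detection floor, so the size of the MpBHLH51 rise is uncertain.

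Of 13 WRKY factors tested, 12 were higher and 1, MpWRKY8 (chosen after its value was seen), was lower, with a median log2 fold change of 2.35 (camera adjusted p = 2.13e-05, or 0.461 with the correlation between genes estimated for each list). Histone and replication genes went down, with 26 of 41 lower, 1 higher (MpCYCD_2, chosen after its value was seen) and 14 not called (median -0.62, camera adjusted p = 6.95e-06, or 0.461 with estimated correlation). MpMCM6 (Mp4g14930), a replicative helicase subunit, fell by 2.18 and MpH2A.W.2 (Mp3g00840) by 1.13. The 4 chlorophyll synthesis genes tested were lower (median -0.90, camera adjusted p = 0.00385, or 0.461 with estimated correlation), MpGUN5 (Mp8g10280) by -1.10 and MpCHLD (Mp6g04260) by -1.05. Of 111 class III peroxidases, 13 were higher, 48 lower and 50 not called (median -0.81, camera adjusted p = 0.00352, or 0.701 with estimated correlation), although MpPOD161 (Mp7g19390) rose 5.13 ± 0.21. Dirigent proteins, laccases and polyphenol oxidases, which act on phenolic compounds, had 37 of 83 higher, 13 lower and 33 not called (median 0.24, camera adjusted p = 0.00385, or 0.461 with estimated correlation). Reads of similar family members may be shared, so the values of single dirigent proteins, peroxidases and polyphenol oxidases are less certain than those of their lists. MpPPO22 (Mp5g18380) went from 102 ± 8.64 to 1969 ± 123 CPM, and MpDIR39 (Mp5g16510) from 0.527 to 366 ± 62.9 CPM. Abscisic acid and desiccation genes had 27 of 73 higher, 8 lower and 38 not called (median 0.63, camera adjusted p = 0.0419, or 0.777 with estimated correlation). MpDHN2 (Mp4g06390), a dehydrin, rose 4.17 ± 0.14. Genes of the male V chromosome had 2 of 40 higher (MpVg00923 and MpVg01095, chosen after their values were seen), 20 lower and 18 not called (median -0.32, camera adjusted p = 0.00178, or 0.461 with estimated correlation). Adjusted over the list alone, each of these 7 lists gave the same counts. Lipoxygenase and CYP74 genes as a list were not called (8 higher, 3 lower, 6 not called, also adjusted over the list alone; median 0.79, camera adjusted p = 0.201).

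In the edgeR quasi-likelihood test, 7539 of 13726 genes (54.9%) were called in Tak-1, 4112 higher and 3427 lower, of which 2045 and 602 changed at least 2-fold. Upper-quartile scaling shifted the median of all genes by -0.19 and gave 3122 higher and 5504 lower, so the split between directions follows the scaling. It also moved the medians of the dirigent list to 0.04 and the V list to -0.52 and ended the peroxidase call (camera adjusted p = 0.123), which the test fry did not make either (0.0690). The desiccation call was lost without Tak-1 mock library 1 (0.0779), Tak-1 mock library 3 (0.0790) or wounded Tak-1 library 3 (0.0656).

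The same comparison in the double mutant asked which responses remained with the desaturases mutated. MpLOX2 rose from 195 ± 13.2 to 837 ± 113 CPM (2.10 ± 0.11, adjusted p = 7.19e-09), and MpJAZ from 26.2 ± 0.702 to 120 ± 20.9 CPM (2.20 ± 0.12, adjusted p = 1.09e-08). MpLOX10 (Mp8g09050), a further lipoxygenase, rose from 119 ± 16.6 to 591 ± 103 CPM (2.31 ± 0.16, adjusted p = 1.04e-07). MpERF9 (Mp4g17430), of the ethylene response factor family, rose by 8.55 ± 0.17 from 0.114 CPM (adjusted p = 6.41e-12). The 0.114 CPM lies near the detection floor, so the size of the MpERF9 rise is uncertain. MpPKS/CHS21 (Mp7g14930), named as a polyketide or chalcone synthase, rose by 6.08 ± 0.30 to 127 ± 21.5 CPM (adjusted p = 5.26e-09). MpPPO31 was again at 0 counts in mock and reached 10.6 ± 3.68 CPM, at least 237-fold higher.

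The WRKY list had 13 of 13 higher (median 2.17, camera adjusted p = 2.20e-06, or 0.562 with estimated correlation), with MpWRKY10 (Mp7g06550) up 3.62 ± 0.19. Histone and replication genes had 27 of 41 lower, 14 not called and no higher calls (median -0.51, camera adjusted p = 8.18e-07, or 0.562 with estimated correlation), MpMCM3 (Mp1g17650) falling by 2.08. The 4 chlorophyll genes were lower (median -0.90, camera adjusted p = 0.00270, or 0.562 with estimated correlation), MpGUN5 by -1.21. Desiccation genes had 43 of 73 higher, 7 lower and 23 not called (46 and 8 adjusted over the list alone; median 1.70, camera adjusted p = 8.64e-05, or 0.570 with estimated correlation). Their median log2 CPM was 3.41, 1.06 and 0.11 in mutant mock libraries 1 to 3 against 3.62, 4.77 and 4.08 in wounded libraries 1, A and B. Without mock library 1, 2 or 3 the median rise was 3.56, 1.36 and 1.15. Among the members MpLEA-like59 (Mp8g07630), a late embryogenesis abundant protein, had 1.62 ± 0.312 CPM in mock and 32.0 ± 4.998 CPM after wounding. The dirigent list had 28 of 83 higher, 10 lower and 45 not called (28 and 8 adjusted over the list alone; median 0.20, camera adjusted p = 0.0323, or 0.570 with estimated correlation). V chromosome genes had 2 of 40 higher (MpVg00770 and MpVg00923, chosen after their values were seen), 11 lower and 27 not called (2 and 8 adjusted over the list alone; median -0.17, camera adjusted p = 0.0184, or 0.562 with estimated correlation). Peroxidases were not called as a list in the mutant (13 higher, 13 lower, 85 not called; 12 and 7 adjusted over the list alone; camera adjusted p = 0.311).

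In edgeR's test 7019 genes (51.1%) were called in the mutant, 3919 higher and 3100 lower, 1814 and 416 of them at least 2-fold. Upper-quartile scaling, with a median shift of -0.14, gave 3180 and 4595, and without both unnumbered libraries 4670 genes were called. Upper-quartile scaling moved the medians of the dirigent list to 0.06 and the V list to -0.31. The dirigent call was lost without mutant mock library 3 (0.0653).

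Whether the wound response itself depends on the desaturases was tested as the difference between the responses, mutant minus Tak-1. Genes with lipoxygenase and CYP74 names were among those with lower responses in the mutant. The log2 difference was -0.92 ± 0.15 for MpLOX2 (adjusted p = 0.00408) and -0.96 ± 0.17 for MpCYP74N2 (adjusted p = 0.00681). MpLOX14 (Mp8g12930) stood at 588 ± 43.2 and 504 ± 75.7 CPM in mock and wounded Tak-1 but 492 ± 29.8 and 211 ± 9.94 CPM in the mutant (-0.997 ± 0.14, adjusted p = 0.00184). MpJAZ had -0.74 ± 0.16 (adjusted p = 0.0257), a call lost without Tak-1 mock library 1 (0.0720), mutant mock library 2 (0.0574), wounded mutant library 1 (0.0586) or unnumbered library A (0.0654). MpMGDG (Mp2g10950), a galactolipid synthase, rose from 113 ± 8.05 to 236 ± 27.3 CPM in Tak-1 and stood at 130 ± 7.27 and 156 ± 4.78 CPM in the mutant (-0.79 ± 0.12, adjusted p = 0.00289). MpSQC2 (Mp8g14150), named as a squalene cyclase, rose from 1.85 ± 0.548 to 9.69 ± 1.67 CPM in Tak-1 and had 1.62 ± 0.332 and 1.60 ± 0.301 CPM in the mutant (-2.42 ± 0.36, adjusted p = 0.00289). In the opposite direction, MpPOD116 (Mp5g17120), a peroxidase at 1.52 ± 0.527 and 0.133 CPM in mock and wounded Tak-1, was at 1.15 ± 0.746 and 1.26 ± 0.127 CPM in the mutant (3.56 ± 0.70, adjusted p = 0.0153). The 0.133 CPM lies near the detection floor, so the size of that difference is uncertain.

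**Figure D3:**
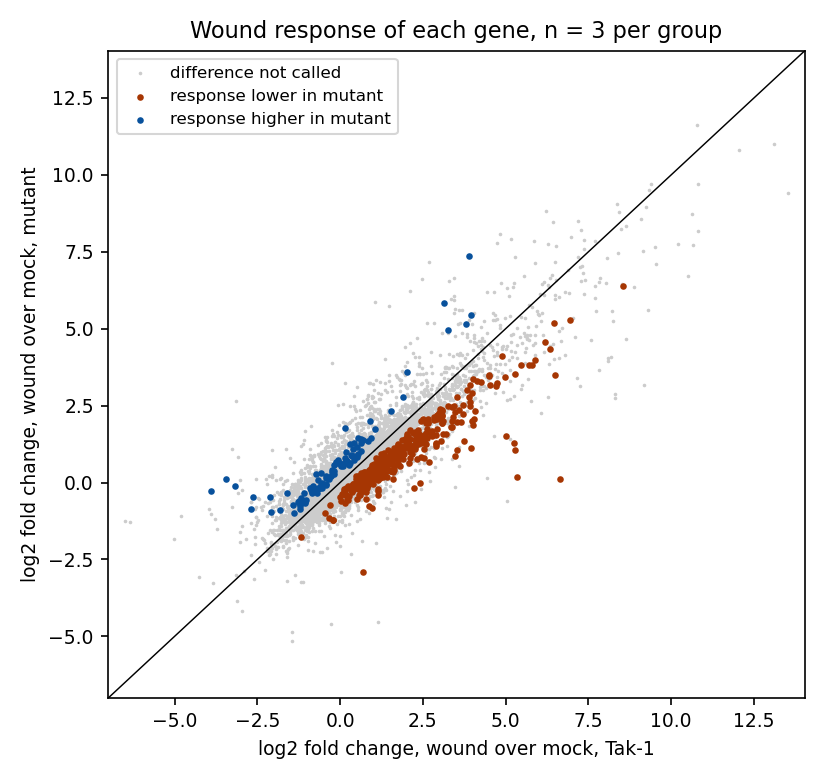
Log2 fold change after wounding of each of 13726 genes in Tak-1 (horizontal) and in the mutant (vertical), with the line of equal response. Genes whose response differed are coloured: 356 had a lower response in the mutant and 95 a higher one.

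Glutathione transferases and transporters of detoxification held 14 of the 356 lower responses against an expected 3.42 (Fisher's exact test, adjusted p = 0.000415 over 50 tests). MpGST38 (Mp2g03760) was at -2.98 ± 0.50 and MpABCC15 (Mp7g13860), an ABC transporter, at -1.25 ± 0.11. The list of 132 had 14 lower, none higher and 118 not called (18 lower and 3 higher adjusted over the list alone), and camera did not call it (adjusted p = 0.0839, or 0.470 with estimated correlation). The lipoxygenase and CYP74 list held 4 lower of 17 (MpLOX2, MpLOX14, MpCYP74N2 and MpLOX4, the last chosen after its value was seen; 5 lower and 1 higher adjusted over the list alone) against an expected 0.441 (Fisher's exact test, adjusted p = 0.0135; camera adjusted p = 0.198, or 0.470 with estimated correlation). Fisher's exact test takes genes as independent draws from all tested genes. Of the 13726 tested 2538 have a symbol, and of the 451 called 132 do. Expected counts of lists defined by symbol may therefore be too low, and the p-values of this test too small. Camera called 5 lists. Terpene and isoprenoid enzymes had 4 of 44 lower (7 adjusted over the list alone): MpSQC2, MpSQS1, MpFTPSL2 and MpMTPSL-like, the last pair chosen after their values were seen (median -0.19, camera adjusted p = 0.000819, or 0.189 with estimated correlation). The dirigent list had 4 of 83 lower (9 adjusted over the list alone): MpPPO20 (Mp4g02130) by -1.72 ± 0.20, MpPPO22 by -0.998 ± 0.15, and MpDIR17 and MpDIR36, chosen after their values were seen (median -0.14, camera adjusted p = 0.000983, or 0.452 with estimated correlation). Peroxidases had 6 of 111 higher (8 adjusted over the list alone; median 0.43, camera adjusted p = 0.000137, or 0.604 with estimated correlation; Fisher's exact test against an expected 0.768, adjusted p = 0.00296). The median response of the peroxidase list was -0.81 in Tak-1 and -0.29 in the mutant, a weaker fall. Desiccation genes had 2 of 73 higher, MpLEA-like4 and MpLEA-like40, with the same count adjusted over the list alone (median 0.77, camera adjusted p = 0.00183, or 0.783 with estimated correlation). The median genotype difference of the desiccation list, mutant over Tak-1, was -1.84 in mock and -0.81 after wounding. V chromosome genes had 0 of 40 called in edgeR, also adjusted over the list alone, 1 at an unadjusted p under 0.05 and 0 called by DESeq2. Their median was 0.10 (camera adjusted p = 0.0495, or 0.470 with estimated correlation).

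**Figure D4:**
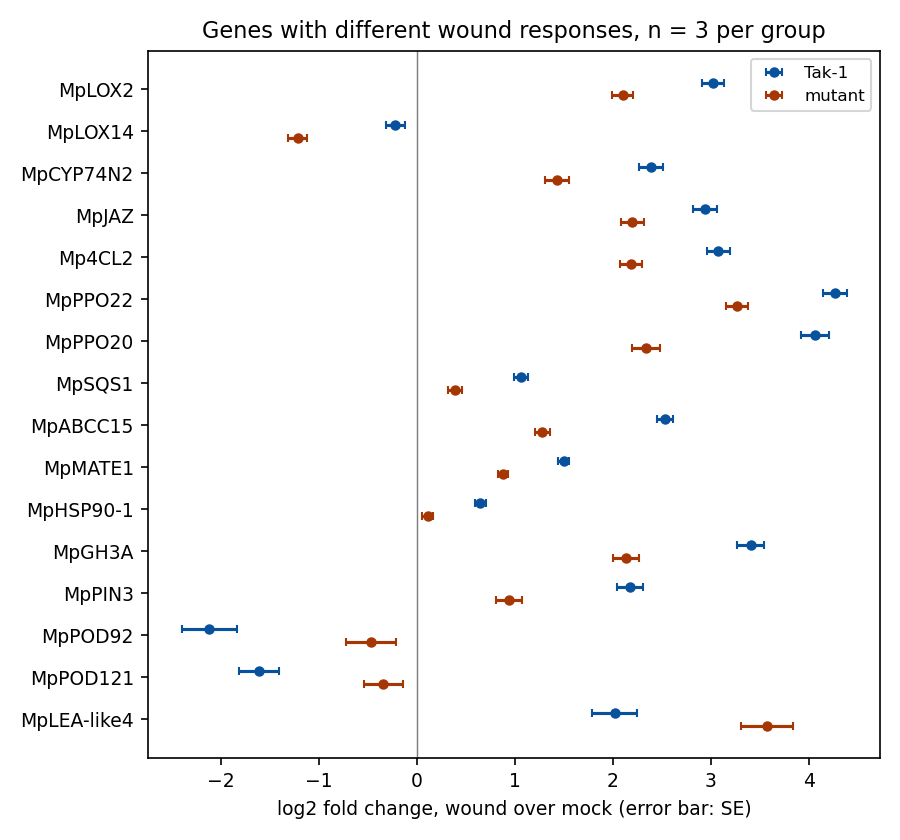
Log2 fold change after wounding (horizontal, error bars SE, n = 3 per group) of 16 genes with different responses, in Tak-1 and in the mutant. MpLOX2, for example, stands at 3.02 in Tak-1 and 2.10 in the mutant, and MpPPO22 at 4.27 and 3.27.

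By edgeR's test of the interaction 451 genes differed, 95 higher and 356 lower, 17 and 113 of them at least 2-fold. DESeq2 called 805, 209 higher and 596 lower. Upper-quartile scaling gave 164 and 293, and medians of -0.08 for the dirigent list and 0.16 for the V list. The test fry did not call the peroxidase (0.276), desiccation (0.373) and V lists (0.169). Leaving out Tak-1 mock library 1, Tak-1 mock library 3 or wounded mutant library 1 gave 295, 290 and 262 genes. The V call was lost without Tak-1 mock library 2 (0.119), wounded Tak-1 library 1 (0.151), mutant mock library 1 (0.137) or wounded mutant library 1 (0.145). MpLEA-like4 was lost without wounded Tak-1 library 1 (0.0644) or 3 (0.0550), mutant mock library 2 (0.0703) or 3 (0.0803), or wounded mutant library A (0.0664) or B (0.0539). MpLEA-like40 was lost without Tak-1 mock library 1 (0.0792), 2 (0.0714) or 3 (0.0760), or wounded Tak-1 library 2 (0.0549) or 3 (0.0578). It was also lost without mutant mock library 2 (0.110) or 3 (0.130), or wounded mutant library A (0.0679) or B (0.0588).

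The size of the responses was compared over the genes called. Among the 4112 genes higher in Tak-1 the median log2 fold change was 0.99 in Tak-1 and 0.79 in the mutant, and 69.3% rose less in the mutant. Genes chosen by a call in Tak-1 favour Tak-1, and among the 3919 chosen in the mutant the medians were 0.94 and 0.90. Of genes called lower in Tak-1 the medians were -0.52 and -0.45, and of those called lower in the mutant -0.48 and -0.51. Both genotypes called 3323 genes higher, where independent lists of these sizes share 1174, and 2520 lower, where independent lists share 774, and 24 genes were called in opposite directions. Across the 13726 genes the responses correlated with r = 0.893, genes not being independent replicates. Of the 356 lower responses, 338 belonged to genes that rose in Tak-1, and 258 of those were also called higher in the mutant. The 338 had medians of 1.64 in Tak-1 and 0.81 in the mutant. Before wounding these 338 genes had a median genotype difference of 0.02, and 19 were called higher and 6 lower in mutant mock plants. Among the 95 higher responses, 28 belonged to genes called higher in both genotypes and 17 to genes called higher in the mutant alone. Another 24 were called lower in both, 22 lower in Tak-1 alone, and 4 lower in Tak-1 and higher in the mutant. A higher response was thus often a weaker fall.

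Whether the genotypes differed before wounding was asked of the mock plants. MpLEA-like4 (Mp1g23200), a late embryogenesis abundant protein, was at 10.9 ± 4.08 CPM in Tak-1 and 2.27 ± 0.493 CPM in the mutant (log2 fold change -2.23 ± 0.27, adjusted p = 0.00116). MpCALEOSIN (Mp5g05270), an oil body protein, was at 4.38 ± 1.67 and 0.286 ± 0.201 CPM (-3.84 ± 0.45, adjusted p = 0.000952). MpCYP707A (Mp2g25940), of the abscisic acid hydroxylase family, was at 5.15 ± 1.51 and 1.18 ± 0.409 CPM (-2.14 ± 0.37, adjusted p = 0.0112). MpPPO22 was lower as well (-0.81 ± 0.11, adjusted p = 0.00256). MpERF17 (Mp4g22280), of the ethylene response factor family, was higher in the mutant, at 15.1 ± 1.499 against 4.68 ± 1.60 CPM (1.68 ± 0.27, adjusted p = 0.00669).

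The abscisic acid and desiccation list had 26 of 73 lower, 45 not called and 2 higher, MpLEA-like11 and MpLEA-like59, chosen after their values were seen (42 lower and 2 higher adjusted over the list alone; median -1.84, or -1.43 with genes of 3 or fewer counts at their bound or ratio; camera adjusted p = 7.46e-15, or 0.231 with estimated correlation). Its replicates were uneven, with median log2 CPM over the list of 4.39, 5.10 and 4.07 in Tak-1 mock libraries 1 to 3 and 3.41, 1.06 and 0.11 in the mutant ones. After wounding the medians were 5.197, 5.31 and 5.28 in Tak-1 and 3.62, 4.77 and 4.08 in mutant libraries 1, A and B. Lipoxygenase and CYP74 genes had 2 of 17 lower (3 adjusted over the list alone; median -0.29, camera adjusted p = 0.0104, or 0.231 with estimated correlation). MpLOX6 (Mp2g12180) was lost without Tak-1 mock library 2 (0.0654), mutant mock library 2 (0.0809) or 3 (0.0715). MpLOX8 (Mp2g12220) was lost without Tak-1 mock library 2 (0.0768) or 3 (0.121) or mutant mock library 1 (0.0533), 2 (0.145) or 3 (0.114). P450 genes had 8 of 89 lower and 81 not called (11 lower adjusted over the list alone; median -0.13, camera adjusted p = 0.00772, or 0.231 with estimated correlation). Chlorophyll genes had 2 of 4 higher, MpGUN5 and MpCHLI1/2-like (4 adjusted over the list alone; median 0.31, camera adjusted p = 0.00189, or 0.254 with estimated correlation). MYB and bHLH factors had 1 of 82 lower, MpBHLH12 (Mp2g05070) at -0.48 ± 0.06 (median -0.07, camera adjusted p = 0.0126, or 0.231 with estimated correlation), and V chromosome genes had 1 of 40, MpVg00020 at -2.07 ± 0.34 (median -0.07, camera adjusted p = 0.0168, or 0.347 with estimated correlation), each with the same count adjusted over the list alone.

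**Figure D5:**
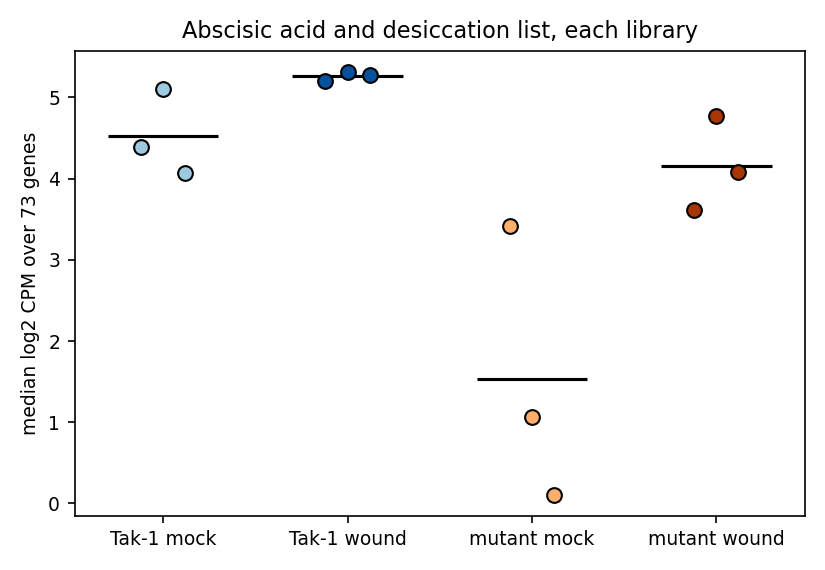
Median log2 CPM over 73 abscisic acid and desiccation genes (vertical) in each library of the 4 groups, with the group mean as a line. Mutant mock libraries lie at 3.41, 1.06 and 0.11, below the Tak-1 mock libraries at 4.07 to 5.10.

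In edgeR's test 620 genes were called in mock, 275 higher and 345 lower in the mutant, 36 and 217 of them at least 2-fold. DESeq2 called 1063, 548 higher and 515 lower, which turned the majority, and a fit on the mock groups alone called 239. The count depended on the libraries used: it was 248, 141 and 490 without Tak-1 mock library 1, 2 or 3, and 730, 139 and 173 without mutant mock library 1, 2 or 3. The MYB call was lost without Tak-1 mock library 3 (0.0835) or mutant mock library 1 (0.0751), and the V call without Tak-1 mock library 2 (0.0834) or mutant mock library 1 (0.188). MpGUN5 was lost without Tak-1 mock library 1 (0.0992) or 2 (0.111) or mutant mock library 2 (0.0985) or 3 (0.0684), and MpCHLI1/2-like without the same libraries (0.152, 0.190, 0.170 and 0.108).

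Whether the mutant's state before wounding resembled a wounded or an opposite state was asked by relating the genotype difference in mock to the wound response of Tak-1, which share the Tak-1 mock libraries. Across genes r was -0.01, against a mean of 0.08 (0.03 to 0.12) in 100 simulations of unchanged groups on the same controls, and the covariance was -0.00868 against 0.00240. Without Tak-1 mock library 3 r was 0.0308, within the 0.0225 to 0.108 of simulations made without that library. Genes higher in both numbered 70, where independent lists share 82.4, and genes lower in both 45, where they share 86.1. Genes higher after wounding and lower in the mutant numbered 147 (103 from independent lists), and genes lower after wounding and higher in the mutant 142 (68.7). In these simulations r was above 0, but both groups were drawn around the measured control means and without any wound response. The error of the control means, which the contrasts share, is therefore left out, and the simulated range cannot decide whether r is unusual.

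The levels reached after wounding were compared last. MpLOX2 stood 1.19 lower on the log2 scale in the wounded mutant (-1.19 ± 0.10, adjusted p = 1.48e-05), MpLOX14 at -1.26 ± 0.10 (adjusted p = 6.93e-06) and MpJAZ at -0.87 ± 0.11 (adjusted p = 0.000213). MpPPO22 had 1969 ± 123 CPM in Tak-1 and 563 ± 50.04 CPM in the mutant (-1.81 ± 0.11, adjusted p = 1.69e-06). MpDIR61 (Mp5g16460), a dirigent protein, had 13.4 ± 1.44 and 1.03 ± 0.177 CPM (-3.69 ± 0.24, adjusted p = 8.28e-06). MpGH3A (Mp6g07600), of the auxin-conjugating family, was at 437 ± 45.8 and 138 ± 28.1 CPM (-1.66 ± 0.13, adjusted p = 6.46e-06). MpPOD88 (Mp5g10690), a peroxidase, was higher in the mutant, at 8.41 ± 2.42 against 2.96 ± 0.117 CPM (2.83-fold, adjusted p = 0.000532).

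Lipoxygenase and CYP74 genes had 7 of 17 lower and 10 not called (9 lower and 2 higher adjusted over the list alone; median -0.73, camera adjusted p = 0.00191, or 0.125 with estimated correlation). The dirigent list had 30 of 83 lower, 51 not called and 2 higher, MpDIR28 and MpPPO10 (31 and 2 adjusted over the list alone; median -0.17, camera adjusted p = 0.000126, or 0.125 with estimated correlation). Glutathione transferases and detoxification genes had 36 of 132 lower and 4 higher, MpABCB2, MpGST14, MpGST27 and MpUGT20 (42 and 7 adjusted over the list alone; median -0.14, camera adjusted p = 0.00219, or 0.125 with estimated correlation). P450 genes had 21 of 89 lower and 2 higher, MpCYP829-like21 and MpCYP97C24 (22 and 2 adjusted over the list alone; median -0.22, camera adjusted p = 0.00191, or 0.125 with estimated correlation). MpCYP94-like (Mp2g10330) stood at -2.08 ± 0.17. Terpene enzymes had 11 of 44 lower and 3 higher, MpCPT2, MpIDS2 and MpMTPSL1 (12 and 3 adjusted over the list alone; median -0.12, camera adjusted p = 0.00604, or 0.125 with estimated correlation). Desiccation genes had 12 of 73 lower and 1 higher, MpLEA-like11 (16 and 1 adjusted over the list alone; median -0.81, camera adjusted p = 0.000256, or 0.534 with estimated correlation). The kinase gene MpSNRK2A (Mp1g24460) was at -0.59 ± 0.07. Peroxidases went the other way, with 17 of 111 higher and 5 lower, MpPOD6, MpPOD18, MpPOD130, MpPOD148 and MpPOD169 (20 and 7 adjusted over the list alone; median 0.37, camera adjusted p = 0.000256, or 0.534 with estimated correlation), as did the chlorophyll genes, 4 of 4 higher, also adjusted over the list alone (median 0.28, camera adjusted p = 0.00604, or 0.347 with estimated correlation). Of these 4, MpCHLI1/2-like was lost without wounded mutant library A (0.0541), and MpGUN4 without wounded Tak-1 library 3 (0.0809) or wounded mutant library 1 (0.0805) or A (0.0856). The members listed here as the few against the direction of their list were chosen after their values were seen.

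In edgeR's test 1996 genes differed after wounding, 691 higher and 1305 lower, 80 and 413 of them at least 2-fold. Upper-quartile scaling gave 1263 and 1151, which turned the majority to the higher side, and medians of -0.06 for terpene enzymes and -0.09 for detoxification genes. The test fry did not call the peroxidase (0.0867) and desiccation lists (0.0748). Without wounded mutant library 1 the number was 1158, and without both unnumbered libraries 887.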

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

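The tests of a single library, of a wound-like state and of the names of the mutated loci were chosen after the results were seen (for the wound-like state 3 choices of genes were tried, and its bound was set after their values were known), while the splits of the samples and the test of a common factor were fixed earlier.

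What follows drew attention because the response to the same wound differed between the genotypes by a test of the difference itself, mutant minus Tak-1. A total of 451 genes differed. Called lists were peroxidases (camera adjusted p = 0.000137), terpene enzymes (0.000819), dirigent proteins with laccases and polyphenol oxidases (0.000983), abscisic acid and desiccation genes (0.00183) and V chromosome genes (0.0495). With the correlation between genes estimated for each list all 5 calls were lost (adjusted p = 0.604, 0.189, 0.452, 0.783 and 0.470, in that order). In 100 splits of the 12 libraries, the real one included, 6 gave as many genes (451 in the real split, 2488 at the highest of the others). As many lists came from 29 splits (5 lists in the real split, 12 at the highest of the others). Chance was not excluded for either count. For genes the share cannot decide, since some splits keep the genotype difference of the wounded plants. The split with 2488 genes exchanges the genotypes of all wounded libraries and turns the genotype difference common to mock and wounded plants into a difference of responses, which points to a structure of the samples. Of the 99 other splits, 7 keep the wounded libraries apart by genotype and 5 of those 7 reach 451, while the other 92 call at most 3 genes and the median over all other splits is 0.

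Genes with higher responses in the mutant, which can be weaker falls, were MpPOD116 (log2 difference 3.56, with wounded Tak-1 near the detection floor), MpLEA-like40 (3.45, a size that depends on the prior count, with 1 count over the mutant mock libraries), MpPOD92 (1.65), MpLEA-like4 (1.56), MpPOD121 (1.27), MpDOXC31 (1.09), MpPOD156 (0.71), MpBHLH12 (0.65) and MpDFR-like4 (0.40). Lower responses in secondary metabolism and detoxification were those of MpGST38 (-2.98), MpSQC2 (-2.42), MpPPO20 (-1.72), MpUGT35 (-1.67), MpKAOL2 (-1.65), MpCYP94-like (-1.62), MpABCC15 (-1.25), MpPPO22 (-0.998), MpCYP97A35 (-0.99), Mp4CL2 (-0.89), MpSQS1 (-0.68) and MpMATE1 (-0.62). In lipid and jasmonate genes they were those of MpLOX14 (-0.997), MpCYP74N2 (-0.96), MpLOX2 (-0.92), MpMGDG (-0.79), MpGPAT6b (-0.76), MpJAZ (-0.74), MpFAD11 (-0.73) and MpFAD5 (-0.49). In signalling, growth and defence they were those of MpPKC2 (-2.82), MpGH16.15 (-1.71), MpERF7 (-1.62), MpGH3A (-1.27), MpPIN3 (-1.24), MpCupin86 (-1.08), MpExpansin16 (-0.94), MpBHLH1 (-0.83), MpCupin84 (-0.63), MpHSP90-1 (-0.54) and MpNOP1 (-0.40).

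Some of these calls were lost with a library left out (adjusted p in brackets, library numbers per group). MpPOD92 was lost without Tak-1 mock 1 (0.0890) or 3 (0.0900), wounded Tak-1 1 (0.0928) or 2 (0.0741), mutant mock 2 (0.0741) or 3 (0.0718), or wounded mutant 1 (0.108) or A (0.0722). MpPOD121 was lost without Tak-1 mock 1 (0.0799) or 3 (0.0777), wounded Tak-1 1 (0.0721), mutant mock 1 (0.0515) or 2 (0.0699), or wounded mutant 1 (0.0899). MpDOXC31 was lost without Tak-1 mock 1 (0.106) or 3 (0.106), wounded Tak-1 1 (0.0635) or 3 (0.0690), mutant mock 2 (0.0930) or 3 (0.0980), or wounded mutant 1 (0.0944), A (0.0833) or B (0.0751). MpPKC2 was lost without Tak-1 mock 1 (0.0578) or 3 (0.0601), or mutant mock 1 (0.0887). MpUGT35 was lost without Tak-1 mock 1 (0.0552) or 2 (0.0578), mutant mock 2 (0.0574), or wounded mutant 1 (0.0570). MpCYP94-like was lost without Tak-1 mock 3 (0.0765), mutant mock 1 (0.0521) or 2 (0.0905), or wounded mutant 1 (0.0545). MpFAD5 was lost without Tak-1 mock 1 (0.0799) or 2 (0.0863), wounded Tak-1 1 (0.0635), 2 (0.0773) or 3 (0.0656), mutant mock 2 (0.0893) or 3 (0.0608), or wounded mutant 1 (0.116) or B (0.0855). MpPOD156 was lost without Tak-1 mock 1 (0.0594) or 3 (0.0614), wounded Tak-1 1 (0.0511), or wounded mutant 1 (0.0662) or A (0.0532). MpCupin84 was lost without Tak-1 mock 1 (0.106) or 2 (0.0838), wounded Tak-1 1 (0.0951) or 2 (0.0576), mutant mock 1 (0.0667), 2 (0.0611) or 3 (0.0720), or wounded mutant 1 (0.0855), A (0.0876) or B (0.0793). MpNOP1 was lost without Tak-1 mock 1 (0.0660), 2 (0.0734) or 3 (0.0671), wounded Tak-1 1 (0.0758), mutant mock 3 (0.0853), or wounded mutant 1 (0.0854). The highest values for MpLEA-like4, MpLEA-like40 and MpJAZ were 0.0803 and 0.130 without mutant mock 3 and 0.0720 without Tak-1 mock 1.

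The first pattern is that 338 of the 356 lower responses belong to genes that rose in Tak-1. A single factor on all rises, as fewer wounded cells in the mutant samples might give, would be 64.7% of the Tak-1 rise. This was taken over 986 genes with at least a 4-fold rise. Of these genes 25.5% lie more than 2 SE from that prediction, 12.9% above it and 12.6% below. That argues against a single factor as the whole explanation, although the share may be too high where few counts make the SE too small. A single library is argued against too, since the lowest number of lower responses with any library left out was 222. Under upper-quartile scaling 293 lower responses stood against 164 higher ones. A smaller common factor beside gene-specific changes, the mutations themselves, and plates or harvest that went with the genotype stay open, since no plate or date is recorded.

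The second pattern is the lower level of abscisic acid and desiccation transcripts in mutant mock plants, whose spread between replicates was wide and whose list call was lost with estimated correlation (camera adjusted p = 0.231). Leaving out Tak-1 mock library 1, 2 or 3 gave list medians of -2.15, -1.49 and -1.41, and leaving out mutant mock library 1, 2 or 3 gave -1.90, -1.86 and -1.65, so no single library carries it. A wound-like state of the Tak-1 mock plants near the size of the full wound response in most wound genes is argued against. The 1776 genes outside the list that rose at least 2-fold in the mutant rose by a median of 1.90. Their median genotype difference in mock was -0.0659 (quartiles -0.389 and 0.145), although the choice by the mutant favours lower values. The medians were -0.0314 and -0.00292 where genes were chosen by both genotypes or by Tak-1. A weaker state of most wound genes stays open, since the bound was set after these values were known and allows for one. A response of some wound genes stays open too, as 138 of the 1776 were called lower and 30 higher in mutant mock plants. Genes higher after wounding in Tak-1 and lower in the mutant numbered 147 against 103 from independent lists, and the reverse 142 against 68.7. Genes higher in both numbered 70 against 82.4, and genes lower in both 45 against 86.1. A difference in the water status of the plants, which may follow from plates or handling, and an effect of the mutations stay open, as neither was recorded or tested.

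The third pattern is the lower MpFAD8 and MpFAD11 in every mutant library, mock and wounded. The lowest Tak-1 and the highest mutant library stood at 55.4 and 21.1 CPM for MpFAD8 and at 499 and 219 CPM for MpFAD11. The explanation that the mutated loci carry other names in the reference table stays open: 2 desaturases were lower in both genotype comparisons, as many as the labels name, but counts hold no sequence. An effect of the mutations on the transcription of other desaturases could give the same values and was not tested.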

How the results depend on the processing

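Tests added after seeing the data were the fits without both unnumbered wounded mutant libraries and camera under the other scalings, filters, own groups and left-out libraries, and the simulations with a library left out, while the block was planned and only the numbering of the unnumbered libraries in it was set later.

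Tak-1 and mutant wound calls, with their higher and lower parts, stayed within 1.5 times under DESeq2 scaling, the DESeq2 test, both filters, the contrast's own groups, both blocks and scaling without the 20 most abundant genes. Upper-quartile scaling gave 5504 lower genes in Tak-1, 164 higher responses in the mutant and 1263 genes higher in wounded mutants, since it shifts the median of all genes by -0.193 in Tak-1 and -0.137 in the mutant. With a 2-fold threshold the counts fell, as fewer genes can pass, to 2647 in Tak-1 (2045 higher, 602 lower), 2230 in the mutant (1814, 416), 130 for the difference (17, 113), 253 in mock (36, 217) and 493 after wounding (80, 413).

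DESeq2 called 805 genes for the difference (209 higher, 596 lower) and 1063 in mock (548 higher, 515 lower, so the majority turned), and the cause was not tested. A fit on the mock groups alone, with fewer libraries to estimate the spread, called 239 (104 higher, 135 lower). Without both unnumbered libraries the lone wounded mutant library is assumed to vary like the other groups, and with fewer samples 4670 genes were called in the mutant (1834 lower), 262 for the difference (26 higher, 236 lower) and 887 after wounding (235 higher, 652 lower). A fit on the contrast's own groups was not run for the difference, which holds all 4 groups.

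With the replicate number as a block, numbering the unnumbered libraries 2 and 3 or 3 and 2, mock calls numbered 369 (135 higher) and 375 (141 higher), and the difference 324 and 368 genes, with 54 higher under the first numbering. The numbers do not pair the samples: deviations from the group mean correlated at -0.141 to 0.190 between libraries of the same number (3 of 12 above 0.1) and at -0.245 to 0.296 between different numbers (7 of 24), and 2 of 10 libraries matched best with their own number.

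With any library left out, calls ran from 6639 to 7189 in Tak-1 (3658 to 3993 higher, 2981 to 3267 lower), 6199 to 6659 in the mutant (3567 to 3860, 2629 to 2863), 262 to 491 for the difference (40 to 152, 222 to 380), 139 to 730 in mock (42 to 314, 95 to 416) and 1158 to 1704 after wounding (343 to 630, 815 to 1204). The difference fell to 295 without Tak-1 mock library 1, 290 without Tak-1 mock library 3 and 262 without wounded mutant library 1. Mock calls fell to 248 and 141 without Tak-1 mock libraries 1 and 2, and to 139 and 173 without mutant mock libraries 2 and 3. Calls after wounding fell to 1158 without wounded mutant library 1. Without mutant mock library 1 the counts rose to 730 in mock and 491 for the difference. Why these libraries weigh more was not tested.

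With the correlation between genes estimated per list, camera called 0 lists in each of the 5 comparisons, with 1, 0, 2, 4 and 5 lists at an unadjusted p under 0.05 (Tak-1, mutant, difference, mock, wounded). Another tool, fry, called 20, 18, 5, 6 and 11 lists, since it tests whether a list moves and not whether it moves more than other genes. Of the lists that camera called it kept 6 of 7, 6 of 6, 2 of 5, 6 of 6 and 6 of 8. Lost were peroxidases in Tak-1 (0.0690), peroxidases (0.276), desiccation genes (0.373) and V genes (0.169) in the difference, and peroxidases (0.0867) and desiccation genes (0.0748) after wounding. For lists that camera did not call, fry gave the opposite direction and a call: in Tak-1 jasmonate signalling (0.00230), MYB and bHLH factors (0.00131) and rhizoid and air pore proteins (0.000468), and in the mutant P450 enzymes (0.000398) and rhizoid and air pore proteins (0.00200). Called lists numbered 6 to 8, 5 to 7, 4 to 7, 4 to 8 and 8 to 9 with a library left out. Other lost calls were the Tak-1 desiccation list (0.0610 at prior count 0.5, 0.0584 unfiltered, 0.0504 under a block), the mutant dirigent list (0.0681 unfiltered, 0.0608 on its own groups), V genes in the mutant (0.0739 unfiltered, 0.117 without both unnumbered libraries), in mock (0.0848 unfiltered) and in the difference (0.0517 to 0.155 under DESeq2 scaling, scaling without 20 genes, both blocks and no filter), and the desiccation list in the difference (0.281 without both unnumbered libraries). The cause was not tested.

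Median responses of genes called higher moved with the choice of genes. In Tak-1 the median was 0.94 over the genes called in the mutant and 0.78 over genes of at least 5 CPM, and in the mutant 0.90 and 0.66. Of genes called lower, the Tak-1 medians were -0.48 under both choices, and the mutant median -0.51 over the genes called in the mutant. With a library left out they ran from 0.98 to 1.11 (Tak-1, higher), 0.77 to 0.86 (mutant, higher), -0.57 to -0.52 (Tak-1, lower) and -0.48 to -0.44 (mutant, lower). The correlation of the mock genotype difference with the Tak-1 response ran from -0.0373 to 0.0308 with a library left out. The mean was 0.0757 in simulations of all libraries. The value lay below each of 100 simulations made for the same libraries, except without Tak-1 mock library 3 (0.0308, simulated 0.0225 to 0.108). Since these simulations leave out the error of the control means and any wound response, they do not decide whether r is unusual.

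Of the named genes, 62 of 64 in Tak-1, 59 of 60 in the mutant, 26 of 40 for the difference, 20 of 41 in mock and 45 of 55 after wounding kept their call under every alternative fit, and 0 reversed. The 2-fold threshold was not applied to single genes here, and some named genes changed less than that. Lost were MpFLV3 in both wound responses (up to 0.182 and 0.104) and MpMID in Tak-1 (0.0526, upper-quartile). Depth sets a floor of 0.0937 to 0.158 CPM, so changes of genes below it were not detectable.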

Other observations

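Tests of neighbouring genes were chosen after the calls had been seen, and the other splits of the samples were fixed earlier.

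Among transcription factors, MpERF21 and MpBHLH4 were close to silent before wounding and rose within 2 h in both genotypes. In Tak-1 MpERF21 (Mp5g22160) went from 0.131 to 236 ± 18.0 CPM (log2 fold change 10.62 ± 0.35, adjusted p = 2.03e-10) and MpBHLH4 (Mp2g00930) from 0.481 to 340 ± 45.6 CPM (9.39 ± 0.29, adjusted p = 1.17e-10), resting on 11 and 38 counts over the mock group. The mutant reached 121 ± 20.3 CPM of MpERF21 and 101 ± 30.0 CPM of MpBHLH4. The test of the difference did not call either response (adjusted p = 0.353 and 0.910), while MpBHLH4 stood lower in the wounded mutant (-1.75 ± 0.17, adjusted p = 3.48e-05). Among signalling and wall genes, MpCML42, a calmodulin-like protein, rose 2.90 ± 0.14 in Tak-1 and 2.34 ± 0.13 in the mutant, with a difference that was not called (adjusted p = 0.138). MpGH16.7 and MpGH16.8, named for the glycoside hydrolase family of xyloglucan enzymes, rose 4.25 ± 0.14 and 3.43 ± 0.11 in Tak-1 and 4.45 ± 0.14 and 3.03 ± 0.11 in the mutant. MpDUO1, named for a sperm regulator, went from 0.390 to 3.15 CPM in Tak-1 (3.01 ± 0.25), and MpPIWIb, of the Argonaute family, reached 14.95 ± 4.85 CPM in the mutant from 4 counts over the mock group.

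MpHMG, of the mevalonate pathway, rose from 192 ± 26.1 to 630 ± 55.2 CPM in Tak-1, whereas MpIDS2, a prenyl diphosphate synthase, fell by 1.15 on the log2 scale. MpFAE2, a fatty acid elongase, rose 2.21 ± 0.10, and MpPLD1, a phospholipase D, rose 2.79 ± 0.17 in the mutant. MpCYP815A1 reached 363 ± 78.7 CPM in the mutant from 3.67 ± 1.68. The auxin carrier gene MpPIN3 rose 2.18 ± 0.14, and MpSAUR3 fell by 2.29. MpHSP90-1 rose from 438 to 686 ± 26.6 CPM in Tak-1 and stood at 438 and 472 ± 3.90 CPM in the mutant. In mock plants MpUGT3 was at 3.62 ± 1.27 CPM in Tak-1 and 0.179 ± 0.147 CPM in the mutant (-4.22 ± 0.61, adjusted p = 0.00433), and MpCHS-like was higher in the mutant (2.32 ± 0.36, adjusted p = 0.00653).

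Lists that camera called in no comparison were these, with the wound response of Tak-1 first. Desaturases had 8 of 14 higher and 3 lower, MpDES6, MpFAD1 and MpFAD9 (median 0.32, adjusted p = 0.400, and 0.402 to 0.848 elsewhere). Jasmonate signalling had MpJAZ and MpNINJA higher and MpCOI1 and MpTPL lower, with a median of -0.12, a mean of 0.52 and a camera direction of down (adjusted p = 0.951, and 0.0914 to 0.900 elsewhere). Phenylpropanoid enzymes had 31 of 79 higher and 18 lower (32 and 18 adjusted over the list alone; median 0.20, adjusted p = 0.400), Mp4CL1 rising 3.93 ± 0.14. Defence proteins had 27 of 104 higher and 18 lower, with a median of -0.07 but a mean of 0.52 and a camera direction of up (adjusted p = 0.951). Heat shock genes had MpHSP90-1, MpHSP90-3 and MpHSP90-4 higher and MpHSF1 lower (median 0.43, adjusted p = 0.400). AP2/ERF factors had 12 of 21 higher and 5 lower, MpAP2B3-1, MpAP2L1, MpAP2L2, MpERF14 and MpERF16 (12 and 6 adjusted over the list alone; median 1.14, adjusted p = 0.0532).

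Calcium signalling had MpCAMTA, MpCBL-A, MpCIPK-A and MpCML42 higher and MpCBL-B and MpCIPK-B lower (median 0.20, adjusted p = 0.910). Cell wall genes had 22 of 87 higher and 28 lower (median -0.13, adjusted p = 0.694). In photosynthesis 1 of 3 was lower, MpFLV3 (median -0.17, adjusted p = 0.706; not called adjusted over the list alone). Lipid genes had 19 of 43 higher and 6 lower (median 0.16, adjusted p = 0.239). Auxin and cytokinin genes had 14 of 42 higher and 12 lower (14 and 13 adjusted over the list alone), with a median of -0.09, a mean of 0.15 and a camera direction of down (adjusted p = 0.807). In sperm and antheridium genes 2 of 3 were higher, MpDUO1 and MpMID (median 0.46, adjusted p = 0.400). Rhizoid and air pore genes had MpARABIDILLO1-2, MpFRH1, MpIRE, MpMRI and MpNOP1 higher and MpFERONIA/MpTHESEUS, MpKAR, MpROP, MpSPIRRIG and MpXCT lower, with a median of -0.07, a mean of 0.26 and a camera direction of down (adjusted p = 0.951). Where no other count is given, that adjusted over the list alone was the same. Members listed here were in part chosen after their values were seen.

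Other splits of the 6 libraries of a contrast number 10 with the real one, too few for a share under 0.05. For genes the real split called 7539 in Tak-1, 7019 in the mutant, 620 in mock and 1996 after wounding, with 0 at the highest of the others, and 1 split was as large in each. For lists the real split called 7, 6, 6 and 8 and the highest of the others 8, 6, 7 and 4, with 2, 2, 2 and 1 splits as large.

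Called genes were neighbours on the chromosomes of MpTak2_v7.1 more often than random placement gives. Genes higher in Tak-1 after wounding (3961 placed) formed 1311 neighbouring pairs, where 1e+05 random placements gave 915 on average and 1010 at most. Lower responses in the mutant (353 genes) formed 23 pairs (7.25 and 21), genes lower in mutant mock plants (338) 38 pairs (6.65 and 20), and genes lower in wounded mutants (1271) 208 pairs (94.1 and 134). The permutation p and its adjusted value were 1e-05 in each of the 4 tests, the smallest the permutations can give. Pairs of the same name stem, as in families from local duplication, were 31, 0, 10 and 16 of these. Only genes with a symbol could be scored for this, 2538 of the 13726 tested, so pairs of duplicates without symbols went uncounted. As an example of nearby members of a family, chosen after the values were seen, MpDIR65, MpDIR61, MpDIR41 and MpDIR39 (Mp5g16440, Mp5g16460, Mp5g16480 and Mp5g16510) were among the 8 largest rises in Tak-1, at 9.09, 13.4, 7.40 and 366 CPM after wounding against 1.46, 1.03, 0.538 and 88.2 CPM in the mutant. Their locus numbers lie close together, but whether they form counted pairs was not checked. Shared regulation of neighbours is a hypothesis that the 1311 pairs may fit, but local duplicates without a symbol could give the same. Overlapping transcripts or shared reads could do so too, since the strandedness of the libraries is not stated. None of these was tested.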
